A study of Mus musculus with 2 samples.

How the data were processed

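ATAC-seq libraries of primary mouse erythroblasts were used, 2 biological replicates of 1 group, each made from 50,000 cells of male C57BL/6J mice aged 5 to 6 weeks, per the labels. The labels give each replicate its own biosample but the same donor identifier, so how far the replicates are independent is not given in the sources used here. The label of replicate 2 lists 2 models of sequencing instrument and that of replicate 1 lists none. With 1 library each, an effect of the instrument could not be told apart from other differences between the replicates. Library preparation, alignment and the peak caller, with their versions and settings, are not given in the sources used here.

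Each replicate had 3 peak lists made from its own alignments, and further lists were made from both replicates, per the labels and the file listings. The lists are named by their output type: thresholded on the irreproducible discovery rate (IDR), pseudoreplicated (longer and less strict), replicated, conservative, and ranked by IDR. The listing names a further parent file of every list but the ranked ones, and its content is not given in the sources used here. Coordinates are in mm10, per the labels, and are printed counting from 1.

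In the deposited lists, each line gives a summit with a whole-number score of at most 1000. The deposited enrichment is the fold of the summit over background as computed by the authors' peak caller. The deposited significance is the −log10 p of the summit by the same caller, and the ranked lists give the −log10 of the global IDR. No step that makes enrichment or significance comparable between lists is given in the sources used here, so both served to rank and group peaks within a list and to describe peaks. The mean and SD of a peak's enrichment over the replicates describe the values of 2 separate lists and were not tested. The lists hold no counts of reads, so the depth of each library is unknown.

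A peak was a distinct interval on chromosomes 1 to 19, X or Y, since an interval with several summits is repeated on as many lines. Its strongest summit gave its place and its motif window. The comparisons used the thresholded list of each replicate. Values are given per replicate or as the mean and SD of 2 replicates. Shares have 95% Wilson intervals, which cover counting error only.

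Overlap between replicates was at least 1 bp and was set against 100 circular shifts of a list within each chromosome. Summits were assigned to promoters (within 1 kb of any annotated transcription start site), exons, introns or intergenic sequence with the GENCODE M21 annotation, and the GRCm38.p6 sequence gave lengths and motifs. Peaks per Mb were counted over bases other than N.

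Gene lists were 5 erythroid lists (globin genes, transcription regulators, heme and iron, membrane and cytoskeleton, receptors with survival and maturation), cell cycle, housekeeping, olfactory receptors and 9 marker lists of other cell types (B cell, T and NK cell, granulocyte and monocyte, macrophage, megakaryocyte and platelet, stem and progenitor cell, hepatocyte, neuron, muscle). All members were matched by symbol but Ahsp, which the annotation does not name so, and Fam132b was matched under its symbol Erfe. A gene was open when each replicate had a peak within 1 kb of any of its start sites. Lists were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 17 lists. As an alternative, 10,000 random lists were matched on the decile of the ratio of observed to expected CpG in the promoter.

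Peaks within 50 kb of the gene's 5' end that were found in both replicates were counted and compared with 10,000 random lists drawn from genes in the same quintile by number of start sites within 50 kb. The permutation test was two-sided and adjusted over the lists. Sequence motifs were sought on both strands within 75 bp of the summit, in windows of 151 bp, and in windows of the same size 1000 bp to each side that overlap no peak. Each of 16 motifs was compared by Fisher's exact test per replicate, adjusted over the motifs, and the less favorable replicate is quoted. The motifs were written as consensus sequences with ambiguity letters, such as WGATAR for GATA.

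Named genes followed a rule: the 4 members of each erythroid list whose promoter peak ranked highest by enrichment and every member not open in both replicates, the 3 open members of each other list that ranked highest, the genes nearest to the 10 peaks of highest rank, the 10 genes with most peaks within 50 kb (1 gene of those with overlapping windows, ties by symbol), and the Hba, Hbb, Gata1 and Klf1 loci. 1 member of the heme and iron list that the rule picks is not reported here. Other names, such as Vwf, Nbeal2, the remaining open markers and the genes with most distal peaks, were chosen after their values were seen. The comparisons, tests, gene lists, motifs, naming rule and most alternatives were fixed before the data were examined.

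Alternatives were the pseudoreplicated lists, the 20,000 most significant lines (lines rather than peaks), each replicate left out, reciprocal overlap of 50%, summits within 100 bp, promoters of 500 or 2500 bp either side, the gene's 5' end only, the list made from both replicates, windows of 20 or 100 kb, peaks over 1 kb from any start site, motif windows of 150 bp either side, up to 50 reorderings of each motif's letters, any base of a peak in place of the summit, and significance in place of enrichment as rank. Similarity to the mitochondrial genome was sought with blastn 2.17.0, and repeated sequence by the share of 31-base words found at more than 1 place in the genome, mitochondrial DNA included.

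Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and pysam 0.24.0, and figures were drawn with matplotlib 3.10.9. The code was tested on simulated data. Overlaps showed 0 differences from a direct count. In 20 simulations of 17 lists over 21,938 genes, the promoter test found 98% of the lists made open and called 1.67% of the others, and the matched test found 100% and called 2.08%. In simulated windows the motif test found 3 of 3 planted motifs. It also called 2 of 13 motifs that were not planted in these windows, and 0.312% of 320 motif tests in 20 simulations without planted motifs. Before planting, simulated summit and flanking windows were drawn with the same base frequencies. False calls from unlike base composition were thus not simulated.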

Results

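Open chromatin was mapped by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in mouse erythroblasts, the nucleated precursors of red blood cells. The cells were primary cells of male C57BL/6J mice aged 5 to 6 weeks. The series held 1 group with 2 biological replicates of 50,000 cells each, so no contrast between conditions could be made. The labels state no aim beyond the assay and the cell type. The comparisons asked how far the replicates shared open sites, where these sites lay, which gene groups had open promoters or nearby sites, and which sequence motifs lay at the summits. The values were lists of peaks in mm10 coordinates. They hold no read counts, so the depth of each library is unknown.

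Erythroblasts of both replicates had a similar number of open sites, and most sites of either replicate were found in the other. The thresholded list held 17,777 peaks in replicate 1 and 18,837 in replicate 2, a mean of 18,307 ± 750 (SD, n = 2). These peaks covered 12.4 Mb and 12.6 Mb, with median widths of 641 bp and 613 bp. Of the peaks of replicate 1, 91.1% overlapped a peak of replicate 2, and 86.3% of the peaks of replicate 2 overlapped a peak of replicate 1 (mean 88.7% ± 3.35, SD, n = 2). When the list of 1 replicate was shifted along each chromosome, the overlap was at most 1.42% in 100 shifts. By bases, the shared sequence made up 75.8% of all sequence covered in either replicate.

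Weak sites were shared less often than strong ones. Among the 5 equal groups of peaks by enrichment, the weakest group overlapped the other replicate in 79.1% of peaks of replicate 1 (95% Wilson interval 77.8% to 80.4%) and in 68.6% of peaks of replicate 2 (67.1% to 70.1%). In the strongest group these shares were 99.6% and 99.7%. Promoter peaks overlapped in 95.2% and 92.6%, against 85.8% and 77.8% of intron peaks. Against the longer, less strict list of the other replicate, 99.3% and 98.7% of the thresholded peaks overlapped, which left 127 and 254 peaks that this less strict list lacked.

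The lists made from both replicates were longer. The thresholded list held 24,717 peaks, of which 15,905 overlapped a peak of each replicate and 4,954 (20%) overlapped none of either replicate's own thresholded list. The latter were weaker, with a median enrichment of 4.76 against 8.75 for those found in both. The list named conservative held 26,050 peaks, more than the thresholded list. It shared 22,961 peaks with the thresholded list, which had 1,756 of its own, and 3,089 were found only in the conservative list.

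Open sites gathered at gene starts. Summits within 1 kb of a transcription start site made up 56.8% ± 0.914 (SD, n = 2) of peaks, while such sequence makes up 6.05% of the genome. Introns held 22.8% ± 0.676 of summits against 38.3% of the genome, intergenic sequence 17.2% ± 0.257 against 52.4%, and exons 3.19% ± 0.0187 against 3.18%. Promoter peaks were a larger share among strong peaks: 83.2% of the strongest group in replicate 1 (82.0% to 84.4%) and 82.4% in replicate 2 (81.2% to 83.6%) lay at promoters, against 45% and 44.2% of the weakest group. In the less strict lists the promoter share was 43.9%, and these shares were not tested across samples.

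Chromosome 11, which carries the alpha globin cluster among many other genes, had the highest density of peaks, 13.95 per Mb ± 0.542 (SD, n = 2). Chromosomes 19 and 17 followed, with 11.3 ± 0.668 and 10 ± 0.231 per Mb. The mean over the autosomes was 7.45 ± 0.307 per Mb. The X chromosome, present once in these male cells, had 2.70 ± 0.0865 per Mb, and the Y chromosome had 11 peaks in each replicate.

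**Figure D1:**
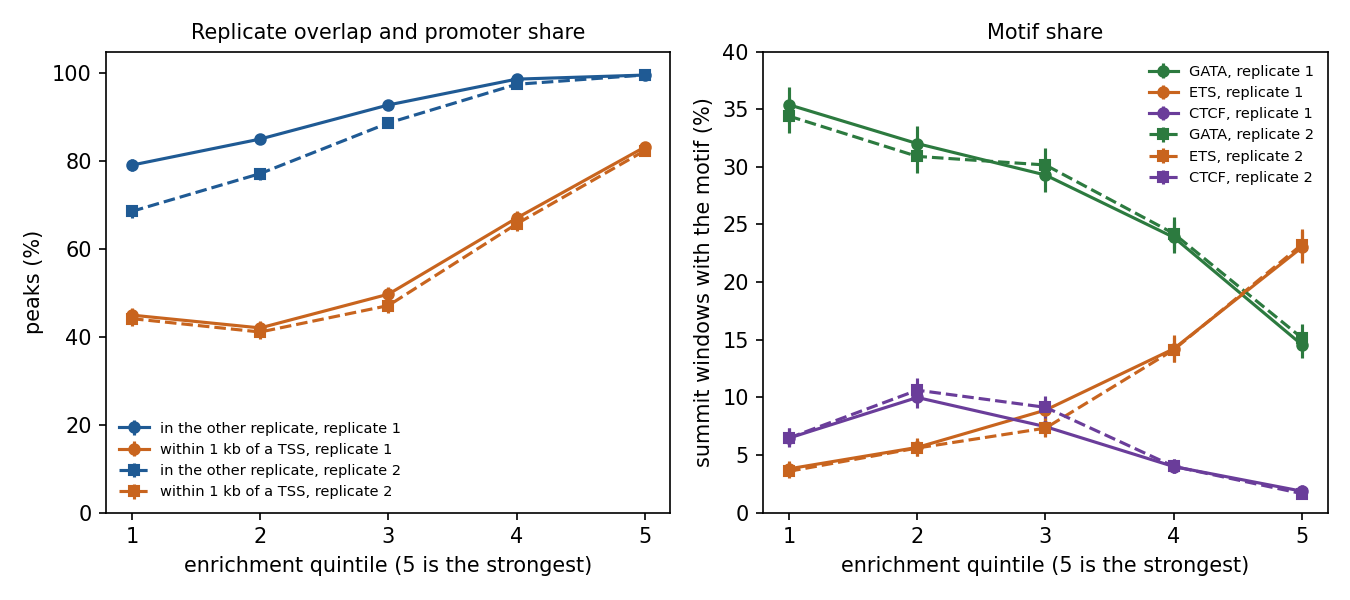
Peaks grouped by enrichment in 5 equal groups (x axis, 5 is the strongest) for each replicate. Left, percent of peaks found in the other replicate or lying within 1 kb of a transcription start site. Right, percent of summit windows with the GATA, ETS or CTCF motif. Bars are 95% Wilson intervals and are often smaller than the points. In the strongest group, overlap with the other replicate is 99.6% and 99.7%, the ETS motif is at 23.0% and 23.2%, and the GATA motif at 14.6% and 15.2%.

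Genes of red cell formation mostly had open promoters in both replicates. A gene was called open when each replicate had a peak within 1 kb of any of its transcription start sites, which held for 9,083 of 21,938 protein-coding genes (41.4%). Open promoters were found for 25 of 26 genes of heme synthesis and iron handling (96.2%), 25 of 27 genes of the red cell membrane and cytoskeleton (92.6%), 21 of 24 erythroid transcription regulators (87.5%) and 18 of 21 erythroid receptor, survival and maturation genes (85.7%). The cell cycle and housekeeping lists had 23 of 23 and 24 of 25 genes open. Globin genes were open in 4 of 10 cases (40%).

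Among heme and iron genes, those with the strongest promoter peaks by enrichment over background included Flvcr1, a heme exporter (13.3 ± 0.278, SD, n = 2, as for all enrichment values of genes below), Ireb2, an iron regulatory protein (11 ± 0.788), and Aco1, a cytosolic aconitase that also binds iron-responsive elements (9.71 ± 0.115). The exception was Alas2, the erythroid form of the first enzyme of heme synthesis (chromosome X, 150547375 to 150570638). Its promoter had no peak in either thresholded list and a peak in the less strict list of both. Within 50 kb of its start lay 6 peaks shared by both replicates, 4 of them over 1 kb from any transcription start site.

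Membrane and cytoskeleton genes with the strongest promoter peaks were Mpp1, a membrane scaffold protein (11.3 ± 0.778), Epb42, which encodes protein 4.2 (9.55 ± 0.0984), Sptb, the erythroid beta spectrin (8.13 ± 0.288), and Add1, an adducin (7.98 ± 0.000636). Those not open were Kcnn4, a calcium-activated potassium channel, and Slc2a1, a glucose transporter. Kcnn4 had a promoter peak in the less strict lists, whereas Slc2a1 had none there either.

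Of the transcription regulators, the strongest promoter peaks were at Sox6 (8.14 ± 0.614), Ldb1, an adaptor of the complex that holds Gata1 and Tal1 (6.77 ± 0.122), Bach1, a heme-binding repressor (6.67 ± 0.241), and Stat5a, which acts downstream of the erythropoietin receptor (6.52 ± 0.0900). The 3 that were not open in both replicates are Gata2 and Myb, regulators active in progenitors, and Bcl11a, a repressor of embryonic and fetal globin genes. Bcl11a had a thresholded peak in replicate 2 alone, with an enrichment of 4.22. Myb had a peak in the less strict lists of both replicates and Gata2 in neither.

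Receptor, survival and maturation genes with the strongest promoter peaks were Bnip3l, needed for the clearance of mitochondria (11.6 ± 0.564), Epor, the erythropoietin receptor (8.49 ± 0.151), Nprl3, whose introns hold alpha globin enhancers (8.45 ± 0.111), and Erfe, the hormone erythroferrone (8.06 ± 0.467). The Nprl3 value is of a peak at a start site inside the gene. At the 5' end of Nprl3 the peak had enrichments of only 4.05 in replicate 1 and 3.95 in replicate 2. Not open were Alox15, a lipoxygenase, Car1, a carbonic anhydrase, and Kit, the stem cell factor receptor. Car1 had a promoter peak in the less strict list of both replicates, Kit in that of replicate 2 alone and Alox15 in neither.

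By Fisher's exact test, two-sided, against all other protein-coding genes, adjusted over 17 lists, the adjusted p was 2.3e-08 for heme and iron genes, 1.1e-07 for membrane genes, 1.9e-05 for transcription regulators and 9.7e-05 for receptor and maturation genes. It was 1.3e-08 for cell cycle and 4.1e-08 for housekeeping genes, so open promoters were not particular to erythroid lists. Promoters rich in CpG were open more often, from 2.60% of genes in the lowest decile of CpG ratio to 73.8% in the highest. In random lists matched on that ratio the mean open share was 48.5% for heme and iron genes, 39.5% for membrane genes, 51.3% for transcription regulators and 48.8% for receptor genes. The matched permutation test gave an adjusted p of 0.00057 for the first 3 of these lists, which is the smallest it could give for them, and 0.00085 for receptor genes.

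Globin promoters followed the adult genes. The open promoters were those of the adult beta globin genes Hbb-bs (ENSMUSG00000052305.6, enrichment 5.06 ± 0.271) and Hbb-bt (ENSMUSG00000073940.3, 4.51 ± 0.158) and the adult alpha globin genes Hba-a2 (ENSMUSG00000069917.7, 3.55 ± 0.0801) and Hba-a1 (ENSMUSG00000069919.7, 3.33 ± 0.0616). The embryonic genes Hba-x, Hbb-y and Hbb-bh1 had no promoter peak in the thresholded or the less strict lists. Hbb-bh2, Hbq1a and Hbq1b had one in the less strict lists of both replicates, and Hbq1a also in the thresholded list of replicate 2.

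The share of open globin genes, 40% (95% Wilson interval 16.8% to 68.7%), did not differ from that of all other genes by Fisher's exact test (adjusted p = 1). Globin promoters are poor in CpG, and random lists matched on CpG were open in 10.3% on average, which turned the direction of the difference (adjusted permutation p = 0.031). Globin genes lie in clusters, whereas random lists drew genes individually, so this permutation p treats clustered genes as independent.

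**Figure D2:**
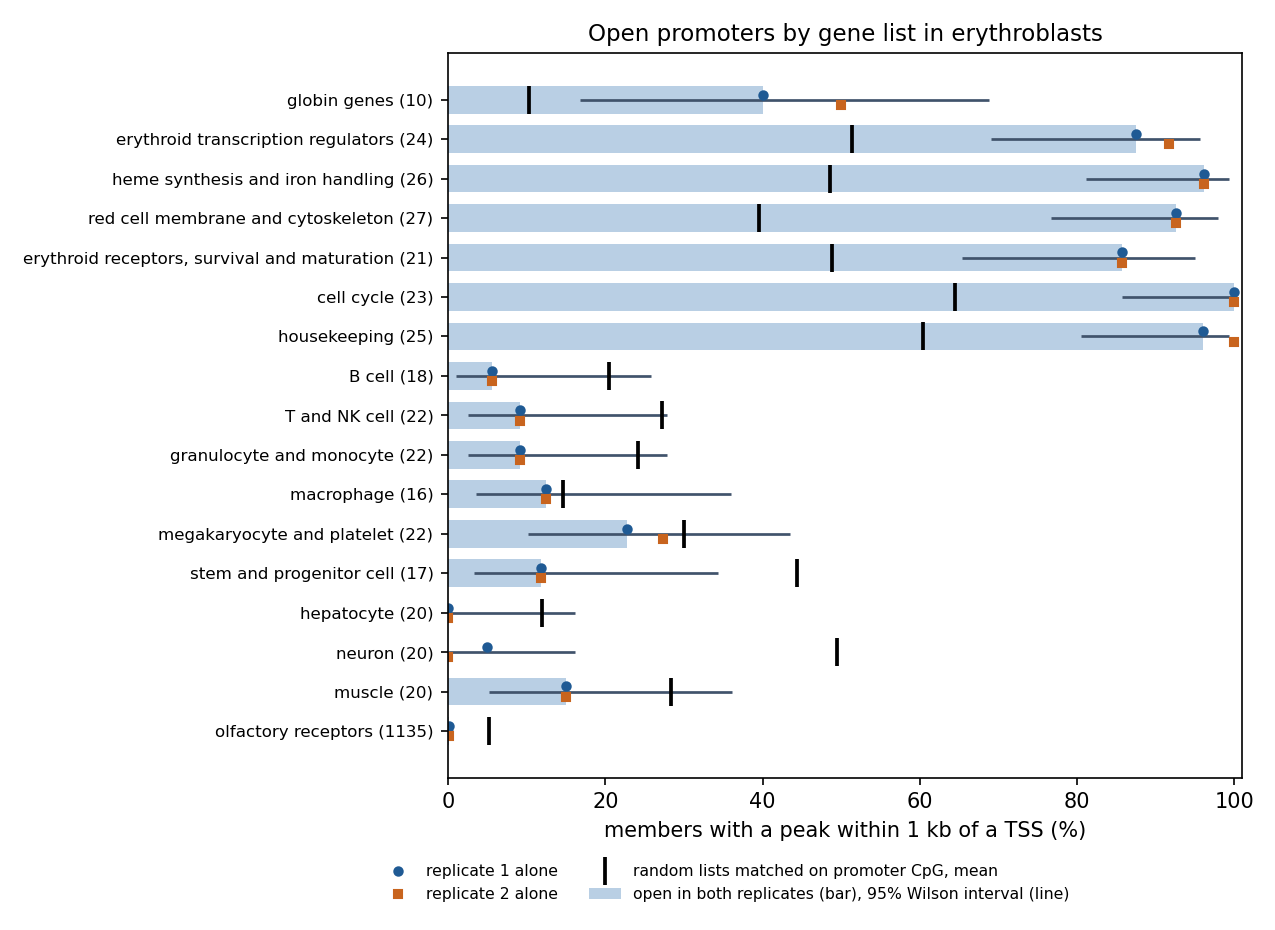
Percent of the members of each gene list (x axis) with a peak within 1 kb of a transcription start site; the number of members stands in brackets. Bars give members open in both replicates with 95% Wilson intervals, points give each replicate alone, and black ticks give the mean of random lists matched on promoter CpG. The 4 erythroid lists other than globin lie between 85.7% and 96.2%, and the 9 marker lists of other cell types between 0% and 22.7%.

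Markers of other cell types mostly lacked open promoters. Of the hepatocyte and neuron markers, 0 of 20 each were open, which allows a share of up to 16.1% by the Wilson interval. Open members numbered 1 of 18 for B cells, 2 of 22 for T and NK cells, 2 of 22 for granulocytes and monocytes, 2 of 16 for macrophages, 2 of 17 for stem and progenitor cells, 3 of 20 for muscle and 5 of 22 for megakaryocytes and platelets. Olfactory receptor genes, which nearly all other tissues keep silent, were open in 2 of 1,135 cases (0.176%).

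Some open promoters of these lists were strong. Foxp3, a regulator of T cells, had a peak of 15.3 ± 0.273 that also lies within 1 kb of a start site of Ppp1r3f. Vpreb1, a part of the pre-B cell receptor, had 10.9 ± 0.536, and its peak also lies within 1 kb of a start site of Top3b. Among macrophage markers Slc40a1, the iron exporter ferroportin (9.62 ± 0.194), and Cd163 (8.5 ± 1.06) were open. Megakaryocyte genes with open promoters were P2ry1 (10.4 ± 0.189), Gp1ba (7.72 ± 0.0390), Itga2b (7.49 ± 0.304), Vwf and Nbeal2. The remaining open markers were Lck, Fcgr3, Mmp9, Runx1, Msi2, Actn3, Casq2 and Ckm, with enrichments from 4.25 at Fcgr3 to 11.1 at Actn3. Olfr67, beside the beta globin cluster, and Olfr56 were the open olfactory genes. With the gene's outermost 5' end as its only start site, the markers Lck, Mmp9, Cd163, Vwf and Casq2 and Olfr56 lost their peak, as did some erythroid genes, Gata1 and Ldb1 among them. With promoters of 500 bp either side, the markers Foxp3, Mmp9, Cd163 and Vwf and both olfactory genes lost it, as did the regulator Gfi1b, and Ckm and the membrane gene Tmod1 kept it in 1 replicate.

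The adjusted p of Fisher's exact test was 6.7e-05 for hepatocyte and for neuron markers, 0.0021 for B cells, 0.0024 for T and NK cells and for granulocytes and monocytes, 0.017 for stem and progenitor cells, 0.024 for macrophages and for muscle, 1.1e-266 for olfactory receptors and 0.091 for megakaryocytes. Matched on CpG, neuron markers (matched mean 49.4%, adjusted permutation p = 0.00057), stem and progenitor markers (44.4%, 0.0064), T and NK cell markers (27.3%, 0.046) and olfactory receptors (5.18%, 0.00057) stayed below random lists. The matched permutation p was 0.15 for B cells, 0.10 for granulocytes and monocytes, 1 for macrophages, 0.19 for hepatocytes, 0.25 for muscle and 0.59 for megakaryocytes, so these lists were not shown to differ from genes with like promoters.

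Erythroid genes were also surrounded by open sites. Within 50 kb of the start of a transcription regulator lay a mean of 6.58 peaks found in both replicates, 3.51 times the mean of random lists drawn from regions of like gene density. Globin genes had 11.6 (2.91-fold), membrane genes 4.89 (2.82-fold), receptor and maturation genes 5.24 (2.47-fold) and heme and iron genes 5.42 (2.46-fold). Cell cycle genes, with 4.04 peaks (2.00-fold), and housekeeping genes, with 4.60 (1.90-fold), had smaller excesses; the difference between lists was not tested. The mean over all protein-coding genes was 2.04.

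Counting only the 6,105 of 16,010 shared peaks that lie over 1 kb from any start site, the excess was 7.24-fold for globin genes, 5.55-fold for transcription regulators, 4.59-fold for membrane genes, 3.95-fold for receptor genes and 3.43-fold for heme and iron genes. For cell cycle and housekeeping genes it was 2.60-fold and 2.38-fold. Two-sided permutation tests with 10,000 random lists gave the smallest adjusted p they could, 0.00049, for the 5 erythroid lists and the cell cycle list when all peaks were counted, and 0.0017 for housekeeping genes. Olfactory receptors had fewer peaks than matched genes (0.177 against 3.10, adjusted permutation p = 0.00049). The adjusted permutation p of the other lists lay between 0.062 for macrophage markers and 0.72, so none of them passed. The 10 globin genes lie in 2 clusters and share the same peaks, so they are not independent.

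Naming only 1 gene of those with overlapping windows, the gene with the most shared peaks within 50 kb was Hist1h2ad, in a histone cluster on chromosome 13, with 20. Afmid had 18, Klf16 17, Cdc25b, a phosphatase of the cell cycle, 16, Dohh 16 and Hba-x, at the start of the alpha globin cluster, 16. Ankzf1, Borcs6 and Ifrd2 had 15 each and Atp5d 14, with ties taken by symbol. Several of these regions hold many genes: 16 protein-coding start sites lie within 50 kb of Hist1h2ad and 7 within 50 kb of Hba-x.

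At the alpha globin locus on chromosome 11, replicate 1 had 16 peaks and replicate 2 had 18 between 32226400 and 32350873. Inside Nprl3 they stood at both ends of the gene, at an exon (32237198) and at intron sites with summits at 32238652, 32245780, 32251025 and 32265263 in replicate 1. The peak at the 3' end of Nprl3 had its summit 0.033 kb from the start of Mpg, with an enrichment of 8.45 in replicate 1. A further peak had its summit at 32256311, at an annotated Nprl3 start site, with enrichments of 8.37 and 8.53. Upstream of Nprl3, towards the globin genes, a peak had its summit at 32269171. Hba-a1 and Hba-a2 each had a wide peak over the promoter and gene body, 1646 bp and 1593 bp long in replicate 1, and a second peak 1.48 kb and 1.45 kb downstream of the start. Between them lay a small peak with its summit at 32293713. Beyond the cluster, peaks at 32321337 and 32324818 had enrichments of 7.38 and 7.91 in replicate 1. Replicate 2 alone had peaks at 32300044, by Hbq1a, and at 32341305.

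The beta globin locus on chromosome 7, from 103762524 to 103903216, held 10 peaks in replicate 1 and 11 in replicate 2. Hbb-bt and Hbb-bs each had a promoter peak and a peak downstream of the start, at 2.37 kb for Hbb-bt and 1.69 kb for Hbb-bs in replicate 1. No peak lay between Hbb-bs and a group upstream of Hbb-y, where the locus control region stands. In replicate 1 the summits of that group were at 103859303, 103861167, 103865904, 103870868 and 103877297, with enrichments of 6.22, 5.05, 5.6, 6.54 and 5.39. The same 5 sites were listed in replicate 2, with 1 more at 103859896. On the other side of the cluster a peak lay at 103793146, by Olfr67.

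**Figure D3:**
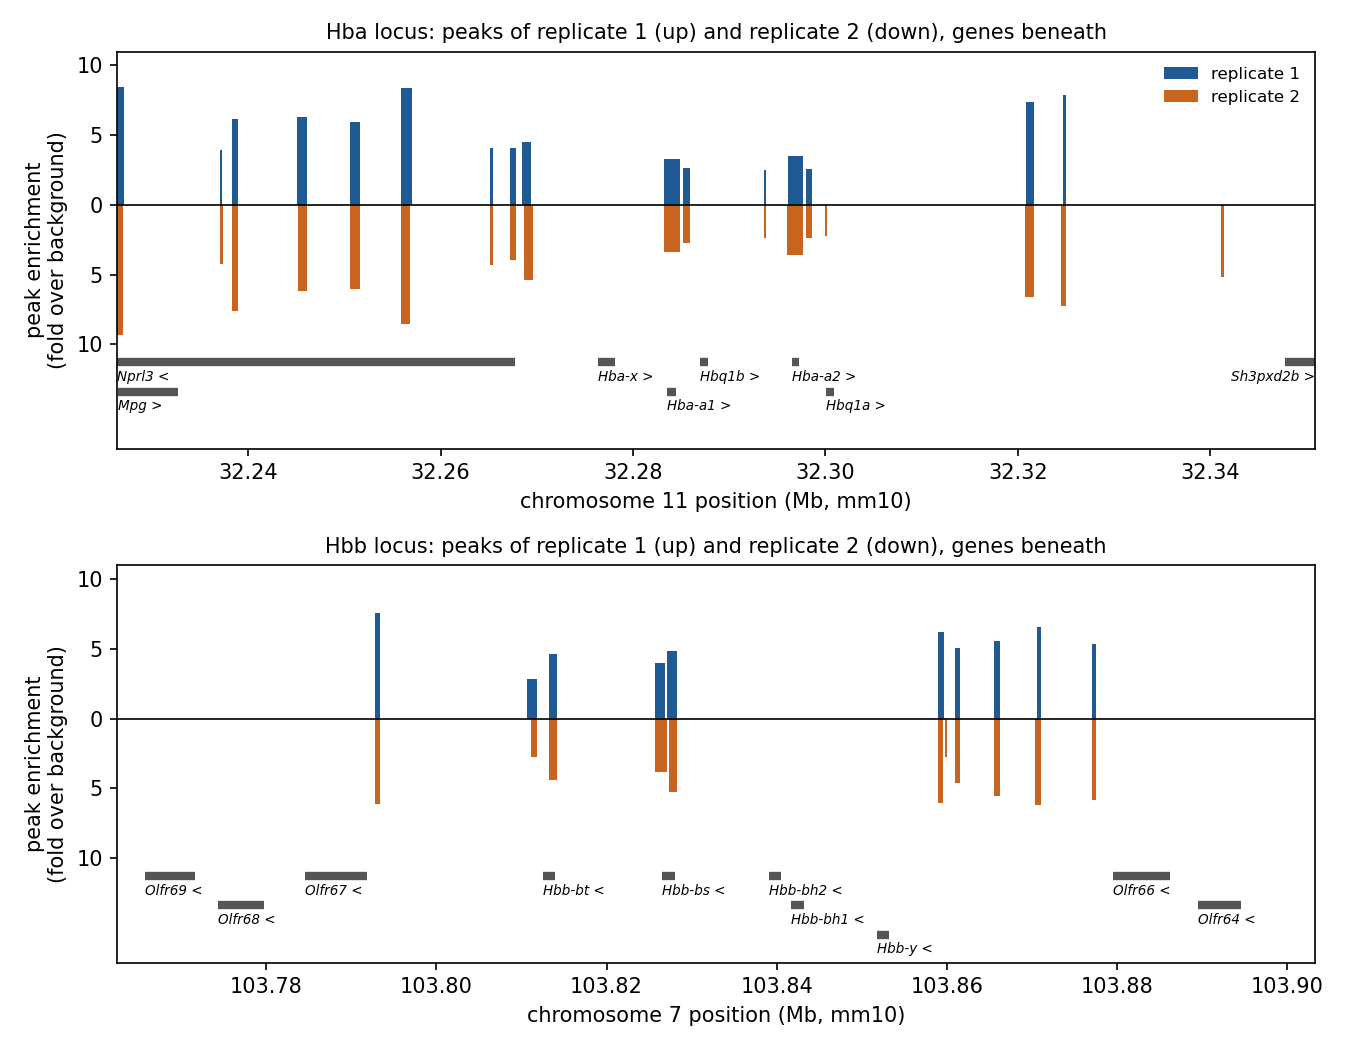
Peaks at the alpha globin (top) and beta globin (bottom) loci along the chromosome (x axis, Mb, mm10). Bars span each peak; their height is the peak's enrichment over background, upward for replicate 1 and downward for replicate 2, and gray lines are protein-coding genes with their strand. Replicate 1 has 16 and 10 peaks, and no peak lies at Hbb-bh1 or Hbb-y.

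Gata1, the erythroid GATA factor on the X chromosome, had 7 peaks in replicate 1 and 6 in replicate 2 in its window. In replicate 1, peaks inside the annotated gene lay 0.077 kb and 3.60 kb upstream of an internal start site of Gata1, with enrichments of 4.63 and 9.20. A pair lay 14.8 kb and 15.4 kb upstream of the outermost start of Gata1, with 12.4 and 8.67. The remaining peaks of replicate 1 lay by Hdac6 (14.8) and by Glod5 (14.75 and 7.01), and replicate 2 lacked the weaker of the last 2. Klf1, which encodes a zinc finger activator of adult beta globin on chromosome 8, stood in a window with 11 and 13 peaks. At Klf1 itself, replicate 1 had a peak 0.617 kb upstream (5.88), another at the start (4.49) and another 1.3 kb inside the gene (4.13). Replicate 2 listed all 3, and the others lay by Farsa, Syce2, Gcdh, Dnase2a, Mast1 and Rtbdn.

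The strongest peaks by enrichment were of another kind. The 10 with the highest rank over both replicates all lay over 1 kb from a protein-coding start site, while 43.8% of all shared pairs of peaks did. First was a peak 13 kb from Abcb11 on chromosome 2, from 69355473 to 69355728, with an enrichment of 38.8 ± 0.297 (SD, n = 2). Next came peaks nearest to Nxph1 (29.7 ± 0.292), G6pd2 (29.2 ± 0.453), Gm12394 (26.3 ± 1.75), Galc (26.4 ± 0.488) and Pak3 (26.2 ± 0.0227). Peaks nearest to Gnb1l, Gm5426, Igf2bp3 and Pdcd1 had 24.1, 23.4, 23.4 and 23.1. Of these, 5 match mitochondrial DNA closely, and those nearest to Nxph1, G6pd2 and Galc lie 940, 1766 and 1155 kb from that gene, so the name only places the peak.

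Motifs bound by erythroid regulators were more frequent at summits than in flanking windows, for the GATA motif alone only by a small excess that turned under other settings, given below. The GATA motif joined to a partial E-box, bound by complexes of Gata1 with Tal1, was within 75 bp of 7.13% ± 0.114 (SD, n = 2) of summits and in 1.04% ± 0.0361 of flanking windows, a ratio of 6.87. The GATA motif WGATAR alone was present at 27.0% ± 0.0430 against 22.8% ± 0.0261 (1.18). The KLF motif, bound by Klf1 among others, was at 27.7% ± 0.0694 against 5.75% ± 0.00497 (4.82), and the NFE2 motif at 1.16% ± 0.00482 against 0.0764% ± 0.00764 (15.2). Flanking windows were not matched on base composition, so these ratios do not separate composition from binding. Reorderings of the KLF letters were at up to 23.5% of summits of replicate 1, against 27.8% for the motif itself. The CTCF motif had the highest ratio, 59.4, at 6.16% ± 0.300 of summits.

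Promoter and distal summits differed. The GATA motif was at 45.2% ± 0.761 of distal summits and 13.1% ± 0.0129 of promoter summits (SD, n = 2), and the GATA and E-box pair at 13.5% ± 0.433 and 2.31% ± 0.0505. In flanking windows of all summits the GATA share was 22.8%, below the distal and above the promoter share. Flanks were not split by location. NFE2 motifs (2.27% against 0.308%), AP1 motifs (8.22% against 2.71%), CTCF motifs (11.5% against 2.06%) and E-boxes (14.5% against 8.47%) were also more frequent at distal summits. The reverse held for ETS motifs (2.06% distal, 17.7% promoter), KLF motifs (16.7%, 36.2%) and the NFY box (16.9%, 31%). Each of these 9 differences passed Fisher's exact test of promoter against distal summits in both replicates, with an adjusted p of at most 6.0e-35. Promoter and distal summits were not matched on base composition either.

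ETS motifs (8.63-fold over flanks), the NFY box (1.37), E-boxes (1.57), AP1 (2.01), PU1 (1.45) and REST (4.40) were above flanks in both replicates. TEAD (0.426) and MEF2 (0.507) motifs were below them. RUNX (1.05, adjusted p = 0.28), OCT (1.05, 0.93) and HNF1 (1.82, 1) did not pass Fisher's exact test, adjusted over 16 motifs, in the replicate with the higher p. For those that passed, the higher adjusted p of both replicates ran from a value too small to represent, for KLF, ETS and CTCF, through 6.8e-25 for GATA, to 0.022 for MEF2. These tests count windows, which are not independent samples.

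Against reordered motif letters at the same summits, GATA, the GATA and E-box pair, KLF, NFE2, AP1 and CTCF exceeded all 50 reorderings in both replicates, but no motif passed after adjustment (lowest adjusted permutation p = 0.10). The number of reorderings limits this test, as its smallest unadjusted permutation p is 0.039. ETS, NFY, E-box, PU1 and REST did not exceed all reorderings. The excess of the GATA motif over flanks turned into a deficit in windows of 150 bp either side of the summit (ratio 0.920) and when every summit line was counted (0.957).

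By peak strength, GATA motifs were at 35.4% of summits in the weakest group and 14.6% in the strongest in replicate 1, and ETS motifs at 3.80% and 23.0%. No test was run across these groups. CTCF motifs were most frequent in the second weakest group, at 9.99%. Among distal summits alone the GATA share was 46.6% in the weakest and 47.1% in the strongest group by enrichment. By significance it was 34.8% and 64.6%.

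**Figure D4:**
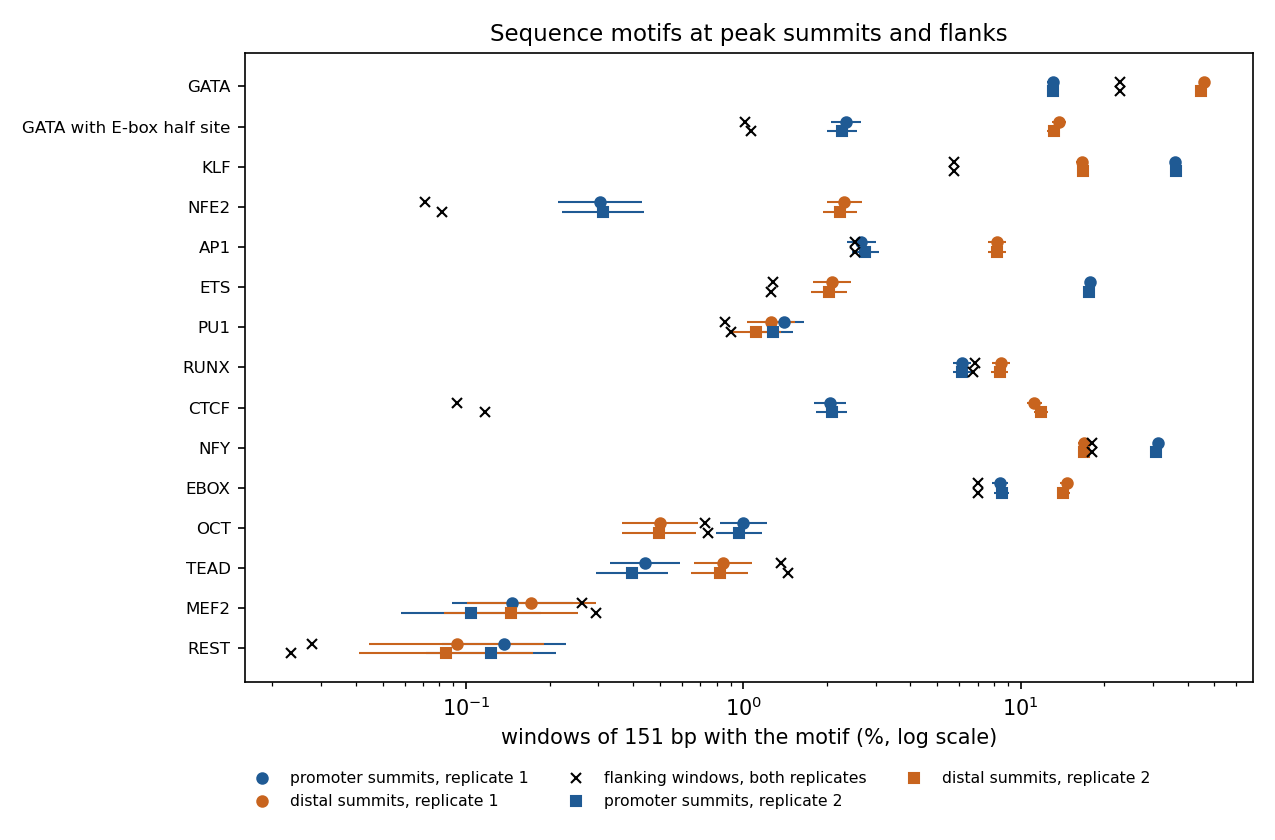
Percent of windows of 151 bp with each motif (x axis, log scale) at promoter summits, distal summits and flanking windows, per replicate. Lines are 95% Wilson intervals, and HNF1, at under 0.02% of windows, is left out. GATA motifs lie at 45.2% of distal and 13.1% of promoter summits, ETS motifs at 2.06% and 17.7%.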

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

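The comparison of the regions below with repeated and mitochondrial sequence was chosen after their number was seen. In the ranked list of replicate 1, 86 regions reach the score of 540 that is the lowest in the thresholded list, yet are absent from that list; in replicate 2 there are 85. They stand out because the score alone would place them in the thresholded lists, and the thresholded lists used for the comparisons lack them. Of the 86 regions, 63 lie on the main chromosomes and 23 on other scaffolds, and of the 85 these numbers are 61 and 24. The thresholded lists hold no region on other scaffolds. Of those on the main chromosomes, 52 in either replicate overlap such a region of the other replicate, so most recur. Their median enrichment is 8.85 and 8.21, taken at the first listed summit of each region rather than its strongest, so it is no higher than that of the strongest summits. Repeated sequence makes up most of 30.2% of them in replicate 1 (95% Wilson interval 20.2% to 42.4%) and 27.9% in replicate 2 (18.2% to 40.2%), and 1 in each matches mitochondrial DNA. Why they are absent from the thresholded lists is not given in the sources used here, and no biological explanation was tested, as the series has only 1 group.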

How the results depend on the processing

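Counting every summit line, leaving out a replicate from the motif shares by location and ranking gene lists by significance were chosen after the data were seen. Peak overlap between replicates stayed far above shifted lists under all 6 alternatives, from 84.2% to 99.0%. The excess of peaks around the 5 erythroid, cell cycle and housekeeping lists and the open promoters of these lists other than globin kept their direction and passed under every alternative. Leaving out a replicate changed no call for these gene lists. The lists hold no read counts, so what depth limits cannot be stated. In the statements below the cause was not tested.

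Ranked by significance, overlap was 54.6% in the weakest and 99.8% in the strongest group, against 73.9% and 99.6% by enrichment. The shares of promoter, exon, intron and intergenic peaks were 58.7%, 5.10%, 19.7% and 16.5% by any base of the peak, 43.9%, 4.10%, 30.0% and 22.1% in the pseudoreplicated lists, 61.2%, 2.82%, 20.6% and 15.4% in the 20,000 most significant lines, 64.9%, 2.70%, 18.2% and 14.2% with every summit line, and 50.8%, 4.39%, 26.3% and 18.5% with start sites within 500 bp.

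The share of open globin genes, 40%, was above that of other genes in place of below it in the pseudoreplicated lists and the list made from both replicates (70.0% each), with promoters of 2500 bp (60.0%), with the 5' end only (40%) and without replicate 1. It ran from 40% to 50% without a replicate. Random lists matched on CpG had 10.3%, less than the list (adjusted permutation p = 0.031, which treats the clustered globin genes as independent). The deficit of open promoters no longer passed in the pseudoreplicated lists for B cells (22.2%) and with 2500 bp for granulocytes and monocytes (22.7%) and muscle (20%). Against random lists matched on CpG it no longer passed for B cells (matched mean 20.4%), granulocytes and monocytes (24.2%), macrophages (14.7%), hepatocytes (11.9%) and muscle (28.4%).

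For the mean number of peaks around a gene, results that had not passed changed direction, still without passing, for T and NK cells with peaks over 1 kb from start sites (0.591), granulocytes and monocytes within 20 kb (0.955), and megakaryocytes (3.18) and muscle (3.20) within 100 kb. The deficit of hepatocyte genes passed within 20 kb (0.200).

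The motif ratio of GATA turned to 0.920 with 150 bp either side and to 0.957 with every summit line. Not passing at first, OCT turned to 0.869 in the pseudoreplicated lists, 0.871 with 150 bp and 0.873 with every summit line, and HNF1 to 0.669, 0.965 and 0.933 under the same settings, with a range from 0.909 to 2.74 without a replicate. RUNX passed in the pseudoreplicated lists (1.13). Against reordered letters no motif passed (lowest adjusted permutation p = 0.10). The few reorderings allow no unadjusted permutation p under 0.039, so a motif could hardly pass and the failure carries little weight. The ratios stayed above 1 for GATA (1.78), the GATA and E-box pair (14.4), KLF (2.96), NFE2 (57.8), AP1 (2.75), CTCF (110), ETS (2.39), PU1 (2.16), NFY (1.45), E-box (1.8) and REST (1.73). There RUNX was 0.920, below in place of above, and TEAD 1.22 and MEF2 1.07, above in place of below.

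Ranked by significance, the low rank of promoter peaks no longer passed for globin genes (54.9), transcription regulators (59.2), heme and iron genes (73.4), membrane genes (67.1) and receptor genes (68.7). For housekeeping genes it turned to 78.5, above all open genes. Of the promoter peaks of 58 list members named by the rule, 9 changed in the pseudoreplicated lists, 6 each with 500 bp, 2500 bp or the 5' end only, and 4 in the 20,000 most significant lines.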

Other observations

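The ranking of genes by distal peaks alone, the comparison of promoter ranks between lists, the count of neighbors of globin promoter peaks and the share of open markers with no gene close by were chosen after the data were seen, whereas the other 7 tests of the 3 patterns below were fixed before the result that each measures. Counting only peaks over 1 kb from any start site, Zfpm1, which encodes the Gata1 partner FOG1, had the most within 50 kb of its start, 11. Cdk5rap3 and Olfr64, beside the beta globin cluster, had 9 each. Hemgn, the erythroid nuclear protein hemogen, Cd47, a red cell surface protein, and Ccl22, Pofut2, Smtnl1 and Wdr26 had 8 each, with only 1 gene of those with overlapping windows named. The mean over all protein-coding genes was 0.576 and the median 0.

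Open promoters of erythroid genes ranked low by enrichment. The median percentile of the promoter peak was 5.93 for globin genes, 21.2 for transcription regulators, 29.4 for membrane genes, 36.6 for heme and iron genes and 37.8 for receptor genes, against 71.3 for all open genes (adjusted permutation p = 0.00045 for the first 4, the smallest it could give for them, and 0.0014 for receptor genes). Cell cycle genes had 74.2 (permutation p = 0.68) and housekeeping genes 55.6 (0.049). By significance the erythroid lists had 54.9, 59.2, 67.1, 73.4 and 68.7 in the same order, against 74.7, and no list passed (lowest adjusted permutation p 0.30).

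The 20 peaks with the highest enrichment all lay over 1 kb from a protein-coding start site, as did 27 of the first 50, against 43.8% of all shared pairs. Regulatory sites like those at other distal peaks are argued against as the source of most of them by the GATA motif, present at 11.1% of these 27 summits and at 44.5% of 1000 other distal peaks (Fisher's exact p = 0.00053). Regulatory sites without the motif are not excluded, as most of the other distal peaks lack it too. A candidate explanation is reads shared between near-identical copies, since 51.9% of the 27 had most of their 31-base words at more than 1 place in the genome, against 7.9% (exact p = 7.3e-09). Of the 27, 3 had both this property and a mitochondrial match, and the genome searched for words included mitochondrial DNA. Without these 3 the share would lie under the mark set before the test, so the candidate is not settled. Reads of mitochondrial origin cannot be told apart for the pattern as a whole: 18.5% matched mitochondrial DNA at 95.5% identity or more, against 0.2% (exact p = 1.7e-07), too few to cover it. With neither property in 11 of the 27, part of the pattern stays open, and with 1 group no biological difference between samples was tested.

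Globin promoter peaks ranked low by enrichment, at percentiles from 1.44 to 17.1, while globin is the main product of these cells. At the same significance, peaks with at least 3 others within 10 kb differed from isolated ones by -32.9 ± 0.292 percentile points (SD, n = 2). All 4 promoters ranked higher by significance than by enrichment. These results met the prediction fixed beforehand for enrichment set against the surrounding signal as the source. That source still cannot be told apart, by a count made after the data were seen. Only 1 of the 8 globin promoter peaks, over both replicates, has so many neighbors. Reads lost between the paralogs cannot be told apart either, since their significance percentiles ran from 44.3 to 76.4, on both sides of the middle of the list. No biological explanation was tested.

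Promoters of 17 of 177 markers of other cell types were open, counting any annotated start site. Of these peaks, 82.4% (Wilson interval 59.0% to 93.8%) had no start site of another protein-coding gene within 1 kb. By a mark set after the data were seen, this argues against a promoter shared with a neighboring gene as the source of most. The test fixed before did not decide it. This share includes Lck, Mmp9, Cd163, Vwf and Casq2, which lost their peak with the gene's 5' end as the only start site. The share without them was not computed, so whether it would still pass that mark is not known. A shared promoter stays open for the other 3 of the 17, Vpreb1, Foxp3 and Actn3 (17.6%, 6.19% to 41.0%), a share not shown to differ from the 26.7% of 9,066 other open genes (Fisher's exact p = 0.58). Cells of another type cannot be told apart for the megakaryocyte list, which had the highest share in the less strict lists, 31.8% (7 of 22, upper bound 52.7%), although Pf4 and Ppbp, both abundant in platelets, had no promoter peak there. For the other marker lists the upper bound was at most 45.2%, under the 50% that had been set as the mark of such cells. A small admixture could leave most markers of a list without a peak, so a share under this mark does not rule out such cells. How many of these markers erythroblasts also express was not analysed here, the labels name no sort, and no biological explanation was tested.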
